A study of Mus musculus with 18 samples.

How the data were processed

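Gene expression was measured in C2C12 cells, an established mouse myoblast line, by BRB-seq, a bulk RNA sequencing method in which the cDNA of each sample is barcoded before the samples are pooled and reads come mainly from the poly(A)-proximal ends of mRNAs. The 18 libraries fell into 6 groups of 3, and the labels numbered the libraries of a group as lots 1 to 3, called replicates here. What a lot is, and whether lots were separate cultures, was not given in the sources used here, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, cells were grown with 20% fetal bovine serum and RNA was extracted from lysates with a column kit. Control cells were lysed in the plate and scraped. Treated cells were washed with PBS and received 200 µL of 0.25% trypsin at 37 °C for 30 s, 3 min or 30 min. In the low trypsin group the trypsin was taken off at once and the cells were kept at 37 °C for 3 min. In the remaining group the cells were shaken for 5 min at 4 °C in a protease that is active in the cold. The first read had 15 cycles and the other read 45.

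Per the submitters' processing notes, the tools used upstream were UMI-tools 1.0.1, cutadapt 2.6, Trim Galore 0.6.6, HISAT2 2.1.0, featureCounts 2.0.1 and DESeq2 1.28.1, with the GRCm38 build. Their settings, the strand used in counting and the treatment of reads with several matches were not given in the sources used here. The authors deposited whole-number counts per gene for 25957 genes, and these counts were used as deposited for every main test. A further deposited table, named as TPM, held values that equalled CPM computed from the counts in 467226 of 467226 cells to within 1e-06, so the deposited values were treated as CPM. The deposited normalized signal values equalled the counts divided by a size factor of 0.797 to 1.30 per library and entered no test. Gene positions on GRCm38 came from the GENCODE M21 annotation, which matched the chromosome of all 10075 tested genes; coordinates are 1-based.

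Library totals lay between 1490869 and 2480690 counts, and 13827 to 15468 genes had a count above 0. At these totals a floor of 3 counts corresponded to 1.21 to 2.01 CPM, and floors cover counting error only. After edgeR's filterByExpr by group, 10075 genes were tested, 9718 of them protein-coding and 159 pseudogenes. They held 99.4% to 99.5% of the counts of each library. The common biological coefficient of variation was 6.08%. Within each group the libraries differed by more than sampling noise in all 18 pairs, with chi-square values of 1.41 to 2.60 per degree of freedom, which does not show that they were separate cultures.

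Each comparison was fitted in edgeR 4.0.16 under R 4.3.3 with TMM scaling, all 18 libraries in a single fit, no covariate, and a quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and "edgeR adjusted p" refers to this test throughout. Fold changes are log2 values with their standard errors (SE). CPM values are TMM-scaled and given as mean ± SD of 3 libraries. The 9 comparisons were each treatment against control, 3 min against 30 s, 30 min against 3 min, low trypsin against 3 min, and cold-active protease against 3 min. An F test over all 6 groups tested the whole design. The smallest p of an exact two-sided permutation test of 3 against 3 libraries is 0.1, so gene-wise calls rest on the model.

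Before the data were examined, 33 gene lists were fixed from general knowledge. They covered immediate early genes, stress responses, cytokines, cytoskeleton and adhesion, myogenesis, mitochondria, ribosomal proteins, cell cycle, metabolism, nuclear-retained RNAs and markers of other cell types. Lists with at least 3 tested members were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry asks only whether the genes of a set move, in balance or in either direction, and does not compare the set with other genes. The genes named were also set by a rule fixed before the data were examined. Per comparison against control, it took the 10 largest fitted rises and the 10 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups, a separation that chance gives in 10% of genes for 3 against 3. Between treatments it took 5 and 5. Predicted genes without a symbol of their own and pseudogenes were passed over. The rule added up to 4 members with the smallest p from each called list and, against control, 10 always-named genes. Of these, Fos and Hspa1a had too few counts to be tested. F2rl1 was not found among the 25957 genes with deposited counts, all of which had a count above 0 in at least 1 library.

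Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile scaling, no filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, the replicate number as a block, leaving out each library in turn, and, for named genes, limma on log2(CPM + 1). A further 3 were chosen after seeing the data. The first tested genes without coding mRNAs of 800 nt or less. The second tested only coding genes without a near-identical copy (no noncoding genes). The third removed from each library its trend with mRNA length. That trend was a natural spline with 6 degrees of freedom fitted on 3299 coding genes with log2 CPM above 6. The fitted genes included members of the ribosomal and respiratory chain lists, so this setting may also remove part of the lists' own change. A near-identical copy was another gene with a match of at least 100 nt at 95% identity or more, found with BLAST 2.17.0. For coding genes the match was to the last 400 nt of the isoform nearest the median length, and for pseudogenes to the whole transcript. Only annotated transcripts were searched, so a gene without a copy may still have an unannotated one. By this search 697 tested coding genes had a copy and 9021 had none. Mapping could split reads between a gene and its copies, so the values of genes with a copy are uncertain. Of 216 named genes with a position, 35 overlapped an exon of another gene within their last 400 nt, 26 of them on the opposite strand, and these are also uncertain.

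Length was measured in 2 ways. The first, the median over the coding isoforms of a gene, was replaced by the length of the principal isoform after the values of single genes had been seen, and the limits of 800 nt and log2 CPM 6 were also set after seeing the values. For short mRNAs outside the ribosomal and respiratory chain lists, medians by both measures are given, while the settings without short mRNAs and with the length trend removed use the second measure alone. The fit was tested on simulated counts for the comparison of 3 min trypsin with control over 9831 genes, where 200 genes were changed. It recovered 18% of genes changed 1.25-fold, 46% at 1.5-fold, 76% at 2-fold and 90% at 3-fold, with 10 false calls among 125. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.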

Results

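Enzymatic treatment of adherent C2C12 myoblasts was compared with direct lysis and scraping in 6 groups of 3 libraries. The treatments were 30 s, 3 min and 30 min in trypsin, a brief wetting with trypsin followed by 3 min without it (low trypsin), and 5 min in a protease that works in the cold. Total counts were 1582906 to 2172214 in the control libraries, 1842214 to 2285307 after 30 s, 1490869 to 1778662 after 3 min, 1608020 to 1884759 after 30 min, 1889521 to 2158249 for low trypsin and 1775288 to 2480690 for the cold-active protease. Mitochondrially encoded genes took 5.39% to 7.09% of the counts of a library and the 10 most abundant genes 11.5% to 13.4%. Each comparison asked which transcripts differed in abundance once the cells had met the enzyme. Treated cells also differed from control cells in wash, incubation and harvest, so comparisons with control do not test the enzyme alone.

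Expression differed among the 6 groups for 1158 of 10075 tested genes (edgeR quasi-likelihood F test, adjusted p under 0.05; 2234 at an unadjusted p under 0.05). Against control, edgeR called 699 genes after 30 s, 399 after 3 min, 472 after 30 min, 523 for low trypsin and 67 for the cold-active protease. The first principal component of log2 CPM held 13.7% of the variance, with the 30 s and low trypsin libraries at its high end. The second held 10.01%, with the 30 min libraries at its low end.

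**Figure D1:**
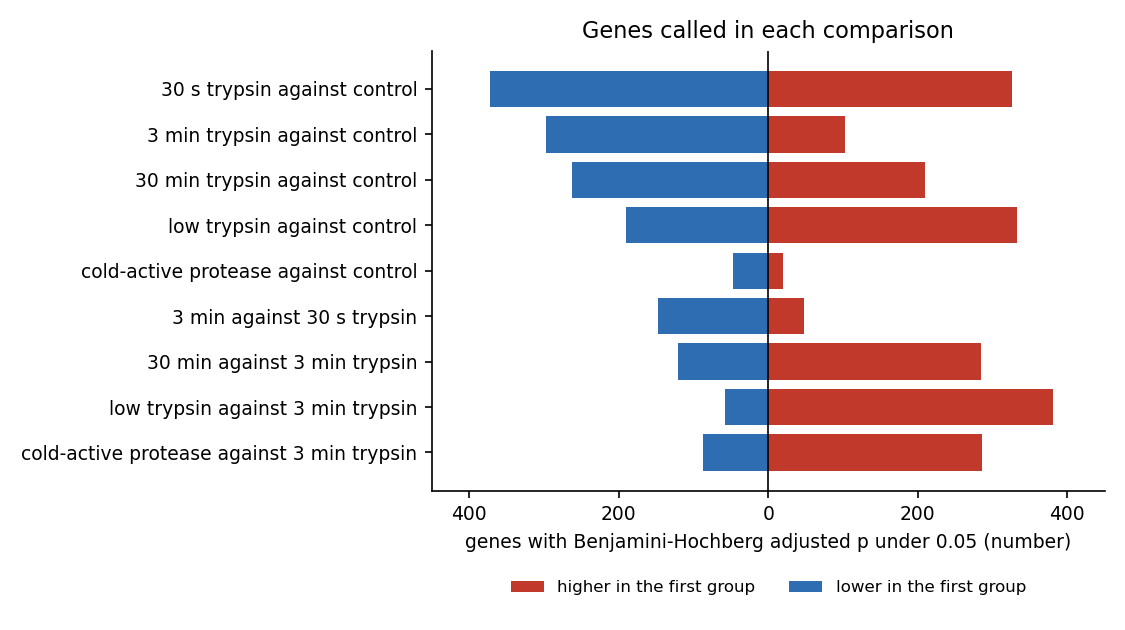
Number of genes called higher (above 0) and lower (below 0) by edgeR in each of the 9 comparisons, from 3 libraries per group. Calls against control ran from 67 for the cold-active protease to 699 for 30 s of trypsin.

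After 30 s in trypsin, most mRNAs for cytosolic ribosomal proteins and many for nuclear-encoded subunits of the respiratory chain were lower than in scraped cells. Of 79 ribosomal protein mRNAs, 61 fell and 8 rose (64 and 9 adjusted over the list alone), with a median log2 change of -0.42 (camera adjusted p = 5.92e-47; adjusted p = 0.00769 with an estimated correlation). It was -0.23 with the length trend removed. Rps16 fell from 545 ± 21 to 241 ± 2.4 CPM, a log2 change of -1.17 ± 0.06 (SE; edgeR adjusted p = 1.18e-20). Rpl32 and Rps14 fell by 0.95 and 0.80 on the log2 scale. All of these have near-identical copies, so their values are uncertain. Of 73 respiratory chain mRNAs, 41 fell and 3 rose (44 and 3 adjusted over the list alone). The median was -0.26 (camera adjusted p = 1.3e-22; adjusted p = 0.00925 with an estimated correlation), and -0.10 with the length trend removed. Cox8a, a subunit of cytochrome c oxidase, fell from 273 ± 29 to 139 ± 5.3 CPM (log2 -0.98 ± 0.08, edgeR adjusted p = 8.93e-14). Ndufb6 and Cox5a fell by 1.36 and 1.18, and Sdhd, which anchors succinate dehydrogenase in the membrane, rose by 1.08 ± 0.11. Many members of both groups have short mRNAs. A set of 108 other coding mRNAs with a principal isoform of 800 nt or less and log2 CPM above 6, called short mRNAs below, had a median of -0.38, with 67 lower and 4 higher, while 3055 longer ones had a median of -0.0035. By the length measure tried first, the median over isoforms, 445 such genes had -0.05. Within the ribosomal list, the 39 members of 800 nt or less had a median of -0.44 and the 40 longer ones -0.39, while the 6 members under 400 nt had 0.54. For the respiratory chain the values were -0.40 for 35 and -0.14 for 38.

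Among 25 immediate early transcription factors, which respond to stimulation without new protein synthesis, 6 rose and 1 fell (6 and 1 adjusted over the list alone). The median was 0.20 (camera adjusted p = 0.00337; adjusted p = 0.0637 with an estimated correlation). Hes1, a Notch target, rose from 52.8 ± 8.7 to 84.7 ± 5.2 CPM (log2 0.66 ± 0.12, edgeR adjusted p = 4.94e-05). Srf, a regulator of actin genes, rose by 0.77 ± 0.18, Junb by 0.33 ± 0.08, Nr4a2 by 0.52 ± 0.14 and Egr1 by 0.36 ± 0.11. Leaving out 1 library ended the call of Srf (edgeR adjusted p = 0.0683 without control replicate 3), of Junb (0.139 without 30 s replicate 1), of Nr4a2 in 3 of the 6 cases (up to 0.129, without control replicate 2) and of Egr1 in 5 (up to 0.224, without control replicate 3). Of 13 mitochondrially encoded transcripts, 7 rose and 1 fell (7 and 2 adjusted over the list alone). The median was 0.17 (camera adjusted p = 0.00337; adjusted p = 0.0637 with an estimated correlation). Without mRNAs of 800 nt or less the median was -0.11 and the list lost its call (camera adjusted p = 0.852). On coding genes without a copy alone, which also drops the noncoding members, the call ended (0.169) at a median of 0.17, and with the length trend removed the median was 0.28. mt-Nd4, a complex I subunit without a near-identical copy, rose from 5783 ± 181 to 6769 ± 152 CPM (log2 0.23 ± 0.04, edgeR adjusted p = 3.46e-05). mt-Co2, mt-Atp6 and mt-Nd3, which do have nuclear copies, rose by 0.99, 1.04 and 1.79.

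A few heat shock genes and 1 muscle differentiation gene fell. Of 21 heat shock genes none rose and 5 fell (1 and 8 adjusted over the list alone). The median was -0.02 (camera adjusted p = 0.0165; adjusted p = 0.0557 with an estimated correlation). Without genes that have a copy the median was 0.01 (camera adjusted p = 0.611), and without mRNAs of 800 nt or less or with the length trend removed it was -0.0061 and -0.0031. Ahsa1, a cochaperone of Hsp90, fell by 0.76 ± 0.14 (edgeR adjusted p = 4.39e-05), as did Hspe1, Hspa8 and Hspb1, which have copies, by 0.79, 0.74 and 0.43. Hspa1b, the inducible Hsp70, did not pass (log2 0.05 ± 0.13, edgeR adjusted p = 0.918). In the muscle list, 1 of 17 fell (2 adjusted over the list alone). The median was -0.33 (camera adjusted p = 0.0156; adjusted p = 0.0557 with an estimated correlation). Removing the length trend gave -0.17 and ended the call (camera adjusted p = 0.102). This was Mylpf, a fast myosin light chain with an mRNA of 766 nt, at -0.70 ± 0.13 (edgeR adjusted p = 4.13e-05). Actc1, Myl4 and Myl1 had values of -0.72, -0.84 and -0.49 and did not pass.

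In total 326 genes rose and 373 fell at 30 s by edgeR, of which 49 and 10 were pseudogenes, and pseudogenes took 0.809 ± 0.045% of counts against 0.595 ± 0.050% in control. With the length trend removed the split was 367 higher and 262 lower. Of called coding genes that fell, 39.7% had mRNAs of 800 nt or less, against 3.29% of those tested. The 10 largest rises by the naming rule were Rps27rt (1.87), mt-Nd3, mt-Tp (1.78), Hoxc8 (1.67), Crtc2 (1.42), Sap18b (1.38), Cep44 (1.282), Cbx3 (1.27), Usp50 (1.21) and Mpst (1.17). Ccn1, named here after its value had been seen, rose from 233 ± 7.6 to 418 ± 14 CPM (log2 0.84 ± 0.07, edgeR adjusted p = 4.83e-15). Crtc2, a coactivator of CREB, went from 16.7 ± 2.2 to 44.6 ± 2.7 CPM (edgeR adjusted p = 2.05e-08). The 10 largest falls were Trmt112 (-1.84), Sh3bgrl3 (-1.77), Polr2j (-1.55), Naa38 (-1.43), Ndufb6, Mir6236 (-1.23), Cox5a, Rps16, Tmsb10 (-1.13) and Mrps21 (-1.13). Of these 20 genes 10 had short mRNAs, 7 of them among the falls, and 7 had near-identical copies. The calls of Usp50, Mpst and Mrps21 ended with 1 library left out, with edgeR adjusted p of up to 0.388 (4 of 6 cases, highest without control replicate 2), 0.126 (3 cases, highest without control replicate 2) and 0.0598 (without 30 s replicate 1).

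At 3 min the same mRNA classes were lower, and few genes were higher. All 54 called ribosomal protein mRNAs fell (61 fell and 1 rose adjusted over the list alone). The median was -0.46 (camera adjusted p = 1.92e-71; adjusted p = 0.000568 with an estimated correlation). Rplp1, a protein of the ribosomal stalk, fell by 0.96 ± 0.06, and Rpl32, Rps12 and Rpl28 by 0.91, 0.81 and 0.93; all have copies. Of the respiratory chain list 48 fell and 1 rose (52 and 1 adjusted over the list alone). The median was -0.52 (camera adjusted p = 4.15e-45; adjusted p = 0.000568 with an estimated correlation). Cox6a1 went from 561 ± 12 to 344 ± 25 CPM (log2 -0.70 ± 0.06, edgeR adjusted p = 5.64e-14), and Uqcrq, Cox8a, Cox6c and Ndufs5 fell by 0.86, 0.96, 0.84 and 1.37. The 108 short mRNAs outside both lists had a median of -0.41, with 64 lower and none higher by edgeR, and by the first length measure the median was -0.07. Ribosomal members had medians of -0.67 when short and -0.34 when longer, and respiratory chain members -0.58 and -0.13. With the length trend removed the list medians were -0.22 and -0.07. Members of both lists entered the fit of that trend, so the drop does not measure the share due to length.

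**Figure D2:**
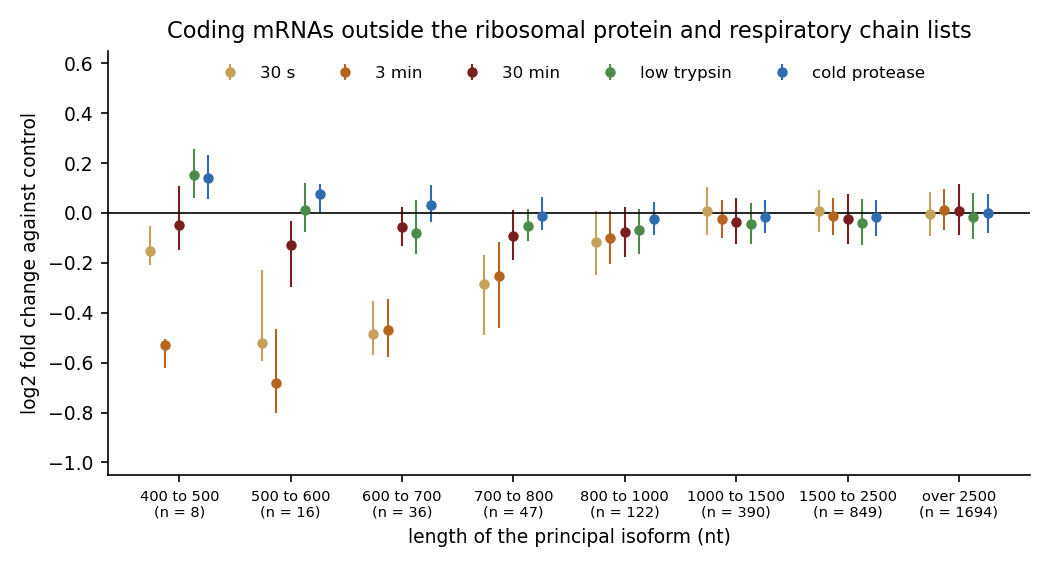
Median log2 fold change against control (points; bars span the quartiles) of coding mRNAs outside the ribosomal protein and respiratory chain lists, by length of the principal isoform, for the 5 treatments, at log2 CPM above 6. The bins drawn under 800 nt, the shortest of 400 to 500 nt with 8 genes, lay lower at 30 s and 3 min; 1 gene under 400 nt is not drawn. All 108 genes of 800 nt or less had medians of -0.38 and -0.41.

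Extracellular matrix and mitotic genes were higher as groups at 3 min. Of 34 matrix genes, 4 rose and none fell by edgeR (6 and 0 adjusted over the list alone). The median was 0.10 (camera adjusted p = 0.00184; adjusted p = 0.0226 with an estimated correlation). Tnc, the matrix glycoprotein tenascin C, rose from 52.4 ± 5.3 to 78.7 ± 9.0 CPM (log2 0.60 ± 0.13, edgeR adjusted p = 0.0011). The calls of Col1a2 (0.21), Thbs1 (0.22) and Hspg2 (0.25) ended in 2, 2 and 4 of the 6 cases with 1 library left out, with adjusted p of up to 0.0535 without control replicate 3, 0.174 without 3 min replicate 2 and 0.231 without 3 min replicate 2. Among 52 G2/M genes, 4 rose and none fell (5 and 0 adjusted over the list alone). The median was 0.10 (camera adjusted p = 0.00981; adjusted p = 0.0218 with an estimated correlation, and 0.0703 without 3 min replicate 3). Hmgb2, a chromatin protein of dividing cells, rose by 0.46 ± 0.09 (edgeR adjusted p = 0.000419). The calls of Kif23, Ckap5 and Cenpf (0.36, 0.42 and 0.34) ended in 2, 3 and 4 of the 6 cases, with adjusted p of up to 0.104 without control replicate 3, and 0.118 and 0.184 without 3 min replicate 2.

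Ccn1, a secreted matricellular protein and target of the mechanosensitive coactivator YAP, rose from 233 ± 7.6 to 405 ± 13 CPM at 3 min (log2 0.79 ± 0.07, edgeR adjusted p = 6.21e-14). Of 21 YAP/TEAD targets 3 rose and none fell by edgeR (5 and 0 adjusted over the list alone). The median was 0.04 (camera adjusted p = 0.0364; adjusted p = 0.0806 with an estimated correlation). Without control replicate 1, control replicate 2 or 3 min replicate 3 the camera adjusted p was 0.0580, 0.0924 or 0.147, and with the length trend removed 0.134 at a median of 0.05. The calls of Amotl1 and F3 (0.38 and 0.54) each ended in 5 of the 6 cases with 1 library left out, with edgeR adjusted p of up to 0.225 without control replicate 2 and 0.276 without control replicate 3. Ccn2 had 0.34 and did not pass. Of 25 immediate early factors 2 rose, Hes1 by 0.65 ± 0.12 and Junb by 0.36 ± 0.08 (2 adjusted over the list alone). The median was 0.16 (camera adjusted p = 0.00961; adjusted p = 0.0980 with an estimated correlation, and 0.0580 without control replicate 1 or 0.0707 without 3 min replicate 3), and 0.11 with the filter of 10 CPM. Of 13 mitochondrially encoded transcripts 3 rose, mt-Cytb by 0.26 ± 0.04, mt-Nd4 by 0.17 ± 0.04 and mt-Nd1 by 0.14 ± 0.04 (5 adjusted over the list alone). The call of mt-Nd1 ended in 4 of the 6 cases with 1 library left out (edgeR adjusted p of up to 0.269, without control replicate 3). The median was 0.14 (camera adjusted p = 0.0364; adjusted p = 0.182 with an estimated correlation). Leaving out control replicate 1, control replicate 2, 3 min replicate 2 or 3 min replicate 3 took that list to 0.0930, 0.0594, 0.0831 and 0.103, and leaving out mRNAs of 800 nt or less to 0.376 at a median of 0.05. Removing the length trend gave a median of 0.32.

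By edgeR 102 genes rose and 297 fell at 3 min, 9 and 11 of them pseudogenes at a pseudogene share of 0.587 ± 0.027%. With the length trend removed 120 rose and 165 fell, and without mRNAs of 800 nt or less 202 genes were called. The 102 rises were 64 with DESeq2 and as few as 50 with 1 library left out (3 min replicate 2). The rises by the naming rule were Zfc3h1 (1.05), Rnaseh1 (0.97), Actg1 (0.97, with copies), Cep44 (0.90), Pogz (0.87), Casp8ap2 (0.87), Inpp5k (0.84), Trrap (0.81), Ccn1 and Ncapd3 (0.76). The falls were Ndufs5, Timm8b (-1.29), mt-Tq (-1.21), Hmga1b (-1.07), H2aj (-1.06), Tmsb10 (-1.03), Naa38 (-1.02), Polr2j (-0.99), Snrpd2 (-0.98) and Rbmx2 (-0.98), 5 of them with short mRNAs. Zfc3h1, a factor of nuclear RNA decay, went from 13.1 ± 3.5 to 27.8 ± 3.9 CPM (edgeR adjusted p = 0.0020). Leaving out 1 library ended the calls of Rnaseh1, Cep44, Pogz, Inpp5k, Trrap, Ncapd3, mt-Tq, Hmga1b, Polr2j and Rbmx2 in 1, 6, 3, 5, 2, 6, 3, 5, 4 and 1 of the 6 cases, with edgeR adjusted p of up to 0.371 for Pogz without 3 min replicate 2.

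After 30 min in trypsin, some genes of the integrated stress response, Hes1 and the chemokine Cxcl1 were higher, and the fall of ribosomal and respiratory chain mRNAs was smaller. Hes1 rose from 52.8 ± 8.7 to 320 ± 25 CPM (log2 2.58 ± 0.10, edgeR adjusted p = 1.82e-26) and Cxcl1, which attracts neutrophils, from 6.13 ± 1.5 to 41.4 ± 1.7 CPM (log2 2.71 ± 0.26, edgeR adjusted p = 1.99e-11). Of 25 stress response genes, 7 rose and 1 fell (11 and 2 adjusted over the list alone). The median was 0.20 (camera adjusted p = 0.000298; adjusted p = 0.0324 with an estimated correlation). Atf4, the transcription factor at the centre of this response, rose from 536 ± 15 to 826 ± 13 CPM (log2 0.62 ± 0.05, edgeR adjusted p = 7.35e-13). Nupr1, a stress-induced chromatin protein, rose by 0.75 ± 0.13 and Chac1, an enzyme that degrades glutathione, by 1.92 ± 0.32. Phgdh, the first enzyme of serine synthesis and an Atf4 target with near-identical copies, fell by 1.43 ± 0.27. Dusp1, a phosphatase of MAP kinases, rose from 13.8 ± 3.6 to 55.1 ± 9.6 CPM (log2 1.96 ± 0.22, edgeR adjusted p = 1.22e-09).

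Some genes of the matrix, nuclear-retained RNA and cholesterol synthesis lists, and 1 FoxO target, also rose at 30 min. Of 34 matrix genes 6 rose and 1 fell (12 and 2 adjusted over the list alone). The median was 0.14 (camera adjusted p = 0.000156; adjusted p = 0.0321 with an estimated correlation). Col12a1 went from 44.5 ± 1.5 to 85.0 ± 14 CPM (log2 0.93 ± 0.13, edgeR adjusted p = 4.95e-07), and Col1a2, Hspg2 and Fn1 rose by 0.35, 0.43 and 0.32. Of 9 genes in the list of nuclear-retained long noncoding RNAs, 3 rose and none fell (5 and 0 adjusted over the list alone). The median was 0.43 (camera adjusted p = 0.000912; adjusted p = 0.0324 with an estimated correlation). These were Snhg1 and Gas5, both snoRNA host genes, at 0.65 ± 0.11 and 0.43 ± 0.10, and Malat1 at 0.58 ± 0.12, whose edgeR adjusted p was 0.0620 without 30 min replicate 2. Where these RNAs lay in the cell was not measured, so the list name does not show that nuclear RNA rose. Kcnq1ot1 had 0.97 and did not pass. Of 21 cholesterol genes 3 rose (4 adjusted over the list alone). The median was 0.15 (camera adjusted p = 0.00854; adjusted p = 0.134 with an estimated correlation, and 0.0620 without 30 min replicate 2). They were the regulator Srebf2 (0.34 ± 0.06), Fdps (0.60 ± 0.14, with copies) and Insig1 (0.50 ± 0.12, edgeR adjusted p = 0.0812 without control replicate 1). Of 17 FoxO and withdrawal genes, Tob1, an antiproliferative protein, rose by 0.77 ± 0.17 (2 genes adjusted over the list alone). The median was 0.23 (camera adjusted p = 0.0118; adjusted p = 0.0428 with an estimated correlation). Txnip, Cdkn1b and Irs2 had 1.47, 0.23 and 0.44 and did not pass.

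Ribosomal protein mRNAs still lay lower at 30 min, with 36 lower and 2 higher (44 and 4 adjusted over the list alone). The median was -0.17 (camera adjusted p = 6.13e-19; adjusted p = 0.0428 with an estimated correlation), -0.10 without genes that have a copy and -0.07 with the length trend removed. Rps6 and Rps16, both with copies, fell by 1.24 and 0.86. Of the respiratory chain list 15 fell and none rose by edgeR (22 and 1 adjusted over the list alone). The median was -0.11 (camera adjusted p = 5.63e-09; adjusted p = 0.0708 with an estimated correlation, and 0.0514 with the length trend removed, at a median of -0.04). Among them were Atp5g1, a subunit of ATP synthase, at -0.76 ± 0.14 and Ndufb6 at -1.21 ± 0.16. The 108 other short mRNAs had a median of -0.08, with 15 lower and 4 higher (-0.03 by the first length measure). Egr1 rose by 0.56 ± 0.11 (edgeR adjusted p = 0.00082) and Atf3, induced by many stresses, by 1.65 ± 0.48 to 6.71 ± 0.37 CPM, a call (edgeR adjusted p = 0.0335) that ended in each of the 6 cases with 1 library left out (up to 0.127, without control replicate 1).

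By edgeR 209 genes rose and 263 fell at 30 min, 22 and 6 of them pseudogenes at a share of 0.660 ± 0.049%. A total of 243 rose and 204 fell with the length trend removed. Without control replicate 2 the count was 304, with 126 rises, and without 30 min replicate 2 the falls were 174. DESeq2 gave 130 rises. The rises by the naming rule were Depp1, an autophagy regulator induced by FoxO, which went from 1.22 ± 0.22 to 13 ± 2.8 CPM (log2 3.35 ± 0.47, not exact since 2 control libraries lay below 3 counts), Cxcl1, Hes1, Dusp1, Chac1, the related chemokine Cxcl5 (1.76), Tcim (1.51), Fam221b (1.34), Snhg12 (1.22) and Stx1a (1.15). The falls were Mrps21 (-1.67), Tspan4 (-1.52), Phgdh, Mir6236 (-1.35), Pnp (-1.32), Ppp1ca (-1.30), Ftl1 (-1.30), Trmt112 (-1.27), Sh3bgrl3 (-1.26) and Eno1 (-1.26). Ftl1, the ferritin light chain, Eno1, a glycolytic enzyme, Mrps21, Phgdh and Trmt112 have near-identical copies, and Ppp1ca, a catalytic subunit of protein phosphatase, does not. The calls of Cxcl5, Stx1a and Trmt112 ended with 1 library left out in 1, 4 and 5 of the 6 cases, with edgeR adjusted p of up to 0.0631 without 30 min replicate 3, 0.193 without control replicate 1 and 0.201 without 30 min replicate 3.

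**Figure D3:**
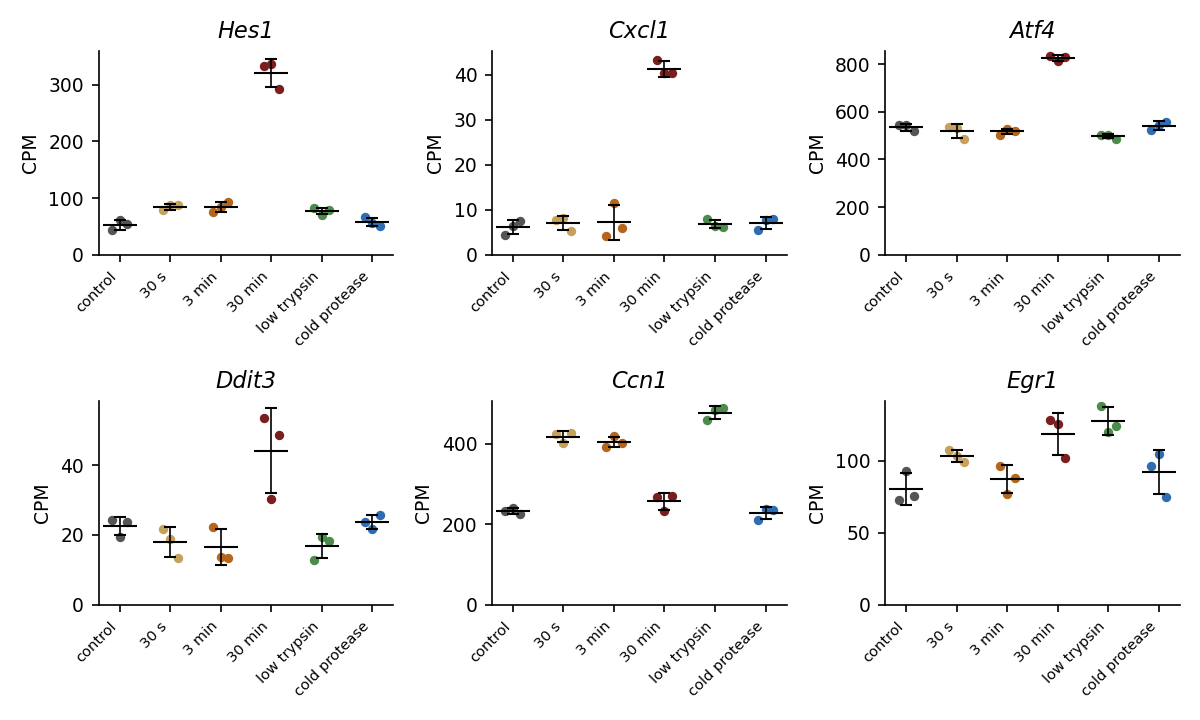
Scaled CPM of Hes1, Cxcl1, Atf4, Ddit3, Ccn1 and Egr1 in each of the 18 libraries (points), with the mean and SD of each group of 3 (bars). Hes1 reached 320 CPM after 30 min of trypsin against 52.8 in control, and Ccn1 reached 418 after 30 s, 405 after 3 min and 477 for low trypsin against 233 in control.

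In low trypsin, 5 of 21 YAP/TEAD targets and 7 of 13 mitochondrially encoded transcripts rose by edgeR. Ccn1 rose from 233 ± 7.6 to 477 ± 16 CPM (log2 1.03 ± 0.06, edgeR adjusted p = 4.26e-18) and Ccn2, its relative, from 82.2 ± 13 to 169 ± 17 CPM (log2 1.03 ± 0.10, edgeR adjusted p = 6.66e-11). With Ankrd1 (0.37 ± 0.06) and F3 (0.82 ± 0.15) among them, 5 of 21 YAP/TEAD targets rose and 1 fell (5 and 1 adjusted over the list alone). The median was 0.08 (camera adjusted p = 0.0078; adjusted p = 0.0342 with an estimated correlation). Of 13 mitochondrially encoded transcripts 7 rose and none fell by edgeR (7 and 1 adjusted over the list alone). The median was 0.38 (camera adjusted p = 1.57e-07; adjusted p = 0.0138 with an estimated correlation). Without mRNAs of 800 nt or less the median was -0.0016, while camera still called the list (adjusted p = 0.0297). mt-Cytb, the cytochrome b gene, rose from 6759 ± 348 CPM by 0.68 ± 0.04, mt-Nd1 by 0.42 ± 0.04 and mt-Nd4 by 0.38 ± 0.04. mt-Co2, which has a nuclear copy, rose from 160 ± 15 to 430 ± 5.4 CPM (log2 1.43 ± 0.07).

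Of 25 immediate early factors 5 rose in low trypsin (6 adjusted over the list alone). The median was 0.09 (camera adjusted p = 0.0390; adjusted p = 0.189 with an estimated correlation). Egr1 went from 80.4 ± 11 to 128 ± 9.6 CPM (log2 0.66 ± 0.11, edgeR adjusted p = 2.53e-05). Hes1 rose by 0.53 ± 0.12, Junb by 0.35 ± 0.08 and Srf by 0.77 ± 0.18 (edgeR adjusted p = 0.0851 without control replicate 3). The camera adjusted p of that list was 0.193, 0.0751, 0.0590 and 0.155 without control replicate 1, control replicate 2, low trypsin replicate 1 and low trypsin replicate 3. Of 28 feedback and signalling genes 4 rose and 2 fell (5 and 2 adjusted over the list alone). The median was 0.16 (camera adjusted p = 0.0178; adjusted p = 0.0804 with an estimated correlation, and 0.0751 without control replicate 2 or 0.0788 without low trypsin replicate 3). Errfi1, an inhibitor of EGF receptor signalling, rose by 0.80 ± 0.10, and Gadd45g and Gadd45b, growth arrest genes, fell by 0.33 and 0.58. The calls of Gadd45b and of Rhob (0.26) ended without control replicate 3 (edgeR adjusted p = 0.222 and 0.154), and that of Rhob in 3 further cases. Ccl2, a monocyte chemokine, rose from 83.4 ± 3.8 to 135 ± 1.9 CPM (log2 0.69 ± 0.09, edgeR adjusted p = 2.05e-07), the 1 called gene of 15 in the cytokine list (1 adjusted over the list alone). The median was 0.13 (camera adjusted p = 0.0333; adjusted p = 0.122 with an estimated correlation). That list lost its call without control replicate 1 (0.0566), control replicate 2 (0.154), low trypsin replicate 1 (0.0505) or low trypsin replicate 3 (0.0851), and its median was 0.19 with the length trend removed.

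Some matrix genes rose in low trypsin, and a few heat shock genes fell. In the matrix list 6 rose and 1 fell (9 and 2 adjusted over the list alone). The median was 0.08 (camera adjusted p = 0.0302; adjusted p = 0.0877 with an estimated correlation, and 0.168 with the length trend removed, at a median of 0.06). Thbs1 rose by 0.40 ± 0.06, Col12a1 by 0.61 ± 0.13, Tnc by 0.54 ± 0.13 and the basement membrane protein Nid1 by 0.31 ± 0.07 (edgeR adjusted p = 0.0646 without control replicate 1). Without control replicate 1, control replicate 2 or low trypsin replicate 3 the list's camera adjusted p was 0.0558, 0.0658 and 0.0807. Of the heat shock list 4 fell (7 fell and 1 rose adjusted over the list alone). The median was -0.08 (camera adjusted p = 0.0023; adjusted p = 0.0185 with an estimated correlation, and 0.117 without genes that have a copy, at a median of -0.05). These were Hspa8 (-0.58) and Hspb1 (-0.28), which have copies, and Ahsa1 (-0.52) and Hspb8 (-0.35). The calls of Ahsa1, Hspb1 and Hspb8 ended without control replicate 2 (edgeR adjusted p = 0.0823, 0.121 and 0.191), and for Hspb1 and Hspb8 in 1 and 4 further cases. In the muscle list Mylpf fell by 0.54 ± 0.12 (5 fell adjusted over the list alone). The median was -0.33 (camera adjusted p = 0.00139; adjusted p = 0.0185 with an estimated correlation). Actc1, Mymk and Acta1 had -0.72, -0.69 and -0.33 and did not pass. Ribosomal protein mRNAs were split into 37 lower and 6 higher (45 and 8 adjusted over the list alone). The median was -0.18 (camera adjusted p = 2.32e-13; adjusted p = 0.0877 with an estimated correlation). Rps4x was at -0.64 and Rps6 at -0.76, both with copies. The respiratory chain list had 11 lower and 2 higher (14 and 3 adjusted over the list alone). The median was -0.04 (camera adjusted p = 0.0496; adjusted p = 0.474 with an estimated correlation). That call ended without control replicate 1, control replicate 2, low trypsin replicate 2 or low trypsin replicate 3 (0.111, 0.181, 0.0946 and 0.462), without genes that have a copy (0.117, median -0.04) and with the length trend removed (0.373, median -0.0066). Without mRNAs of 800 nt or less the median was -0.06. The 108 other short mRNAs had a median of -0.03, with 10 lower and 9 higher (-0.04 by the first length measure).

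By edgeR 332 genes rose and 191 fell in low trypsin (353 and 160 with upper-quartile scaling), of which 60 and 5 were pseudogenes, and the pseudogene share of counts was 0.985 ± 0.018% against 0.595 ± 0.050% in control. Falls were as few as 118 with 1 library left out (low trypsin replicate 2). The rises by the naming rule were Nkain2 (2.41, with 2 control libraries below 3 counts), Tnfsf9 (2.32), Rps27rt (2.24, with copies), Usp50 (1.81), mt-Tp (1.81), Lpcat4 (1.67), Kirrel (1.62), mt-Tt (1.52), Crtc2 (1.52) and Mir17hg (1.51). Tnfsf9, the ligand 4-1BBL, went from 2.78 ± 0.19 to 14.2 ± 1.6 CPM (edgeR adjusted p = 2.83e-05) and Kirrel, an adhesion protein of the nephrin family, from 22.2 ± 1.9 to 67.7 ± 6.6 CPM (edgeR adjusted p = 1.85e-11). The falls were Cox5a (-1.29), Trmt112 (-1.26), Pnp (-1.04), Nsa2 (-1.03), Phgdh (-0.9997), Fabp5 (-0.93), Dhps (-0.92), Sh3bgrl3 (-0.91), Ppp1ca (-0.87) and Ccdc112 (-0.87). Leaving out 1 library ended the calls of Lpcat4, mt-Tt, Mir17hg, Trmt112, Nsa2, Phgdh and Ccdc112 in 2, 1, 1, 5, 2, 1 and 5 of the 6 cases, with edgeR adjusted p of up to 0.282 for Ccdc112 without low trypsin replicate 3. F2r, the thrombin receptor and 1 tested member of the protease-activated receptor list, rose by 0.29 (edgeR adjusted p = 0.0066; called adjusted over the list alone too), and was named after its value was seen.

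The cold-active protease gave the fewest calls, with 20 genes higher and 47 lower by edgeR, 2 and 3 of them pseudogenes at a share of 0.654 ± 0.012%. With the length trend removed 26 rose and 44 fell. Col12a1, a fibril-associated collagen, rose from 44.5 ± 1.5 to 69.8 ± 3.7 CPM (log2 0.65 ± 0.13, edgeR adjusted p = 0.00266), and Ppp1ca fell from 122 ± 1.7 to 78.3 ± 3.1 CPM (log2 -0.65 ± 0.11, edgeR adjusted p = 9.42e-05). Of 34 matrix genes 3 rose, Col12a1 with Col1a2 at 0.34 ± 0.05 and Hspg2 at 0.37 ± 0.07 (4 adjusted over the list alone). The median was 0.09 (camera adjusted p = 0.00217; adjusted p = 0.0372 with an estimated correlation). Among 9 nuclear-retained RNAs 3 rose (4 adjusted over the list alone). The median was 0.38 (camera adjusted p = 6.67e-05; adjusted p = 0.0116 with an estimated correlation). These were Xist (0.87 ± 0.19), Neat1, the scaffold of paraspeckles (0.76 ± 0.15), and Firre (1.37 ± 0.36). Their calls ended with 1 library left out in 2, 2 and 5 of the 6 cases, with edgeR adjusted p of up to 0.342 and 0.0870 without cold-active protease replicate 2 and 0.343 without control replicate 2. Of the heat shock list Hspa8, which has copies, fell by 0.52 ± 0.08 (2 fell adjusted over the list alone). The median was -0.10 (camera adjusted p = 0.000502; adjusted p = 0.0116 with an estimated correlation, and 0.125 without genes that have a copy, at a median of -0.09). Ahsa1, Hsp90aa1 and Hspe1 had -0.43, -0.26 and -0.16 and did not pass. Of the ribosomal list 9 fell (21 fell and 6 rose adjusted over the list alone). The median was -0.04 (camera adjusted p = 0.000502; adjusted p = 0.658 with an estimated correlation, and 0.522 without genes that have a copy, at a median of -0.03), and -0.07 without mRNAs of 800 nt or less. Rps4x, Rps6, Rps16 and Rpl10, all with copies, were at -0.51, -0.73, -0.40 and -0.42. The 108 short mRNAs had a median of 0.04, with 6 lower and 1 higher (-0.0027 by the first length measure).

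The remaining rises by the naming rule for the cold-active protease were Ube2n (0.66), Mustn1 (0.64), Zmynd8 (0.58), Ccnl2 (0.53), Kmt2d (0.45) and Notch2 (0.39). The falls beside Rps6 and Ppp1ca were Abracl (-1.04), Sh3bgrl3 (-0.84), Supt4a (-0.78), Ctxn1 (-0.77), Bcl7c (-0.77), Ftl1 (-0.70), Nudt21 (-0.69) and Btf3 (-0.65). Leaving out 1 library ended the calls of Ube2n, Mustn1, Zmynd8, Ccnl2, Kmt2d, Notch2, Supt4a, Ctxn1, Bcl7c, Nudt21 and Btf3 in 5, 4, 5, 5, 4, 3, 6, 6, 4, 1 and 4 of the 6 cases, with edgeR adjusted p of up to 0.338 for Ccnl2 without control replicate 3. The number of calls was 41, 43, 35 and 39 without control replicate 2, control replicate 3, cold-active protease replicate 1 and cold-active protease replicate 2, and with 1 library left out rises were as few as 9 and falls as few as 26. Cirbp, a cold-inducible RNA-binding protein, did not pass (49.7 ± 5.4 CPM in control and 51.0 ± 12 after the cold-active protease, log2 0.05 ± 0.16, edgeR adjusted p = 0.966).

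**Figure D4:**
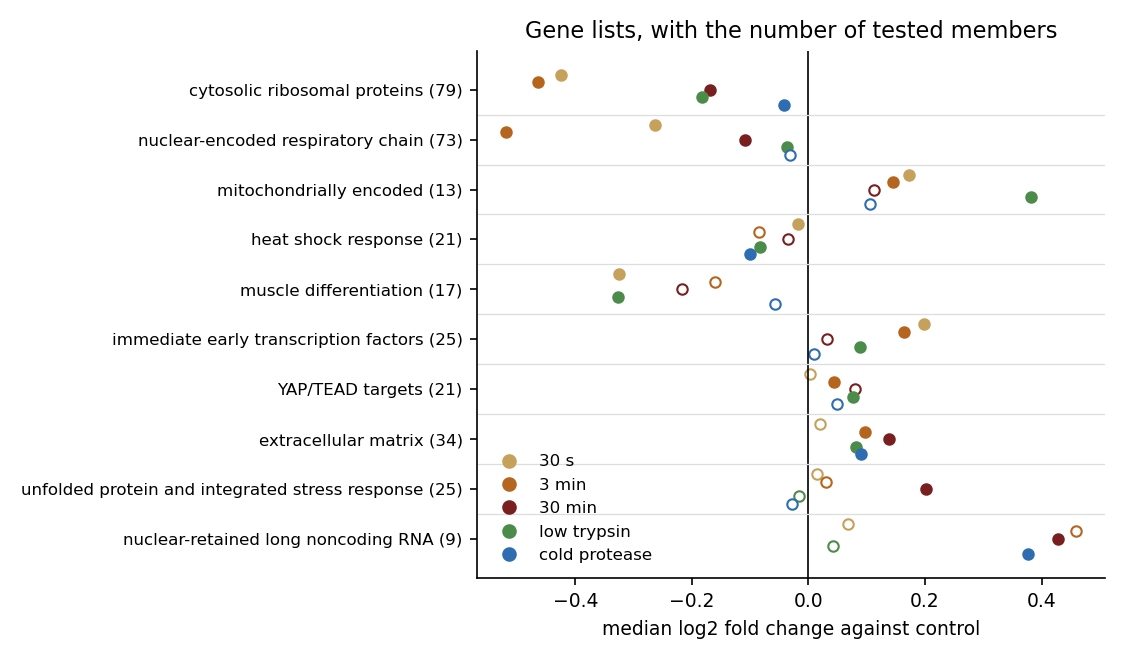
Median log2 fold change against control of the tested members of 10 gene lists for the 5 treatments; filled points had a camera adjusted p under 0.05 and open points did not. Ribosomal protein mRNAs had medians of -0.42 and -0.46 at 30 s and 3 min, and -0.17 at 30 min.

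Between 30 s and 3 min of trypsin, transcripts of several small ribosomal proteins that had been above control at 30 s fell. Rps29, Rpl37, Rps21 and Rpl39, of which Rpl37 has no near-identical copy, fell by 0.88, 0.58, 0.62 and 0.71 on the log2 scale. Rps29 had 199 ± 16 CPM in control, 414 ± 1.9 at 30 s and 225 ± 14 at 3 min, and Rpl39 had 247 ± 12, 398 ± 30 and 244 ± 7.4. Rpl37 and Rps21 ended below control at 3 min by edgeR. Plau, the urokinase plasminogen activator, fell from 71.8 ± 3.5 to 33.2 ± 5.5 CPM (log2 -1.11 ± 0.16, edgeR adjusted p = 1.58e-06). By edgeR 48 genes rose and 147 fell, 2 and 38 of them pseudogenes at shares of 0.587% against 0.809%. A total of 61 rose and 121 fell with the length trend removed, and 129 genes were called without mRNAs of 800 nt or less. Rises were as few as 29 with 1 library left out (30 s replicate 2). Of the ribosomal list 9 rose and 22 fell (20 and 29 adjusted over the list alone). The median was -0.03 (camera adjusted p = 0.0389; adjusted p = 0.947 with an estimated correlation). Without short mRNAs the median was 0.07 (camera adjusted p = 0.891), with the length trend removed 0.05 (0.755) and without genes that have a copy -0.0096 (0.358). That call ended without 30 s replicate 1 (0.103), 30 s replicate 2 (0.0696), 3 min replicate 1 (0.0945) or 3 min replicate 2 (0.279). Of the respiratory chain list 16 fell and 1 rose (23 and 4 adjusted over the list alone). The median was -0.08 (camera adjusted p = 7.08e-06; adjusted p = 0.265 with an estimated correlation, and 0.619 with the length trend removed, at a median of -0.01). Uqcr11, Cox6c, Cox7c and Ndufa2 fell by 0.68, 0.63, 0.47 and 0.46, and the 108 other short mRNAs had a median of 0.01 (-0.0085 by the first length measure). Of the matrix list 3 rose (4 adjusted over the list alone). The median was 0.09 (camera adjusted p = 0.00803; adjusted p = 0.122 with an estimated correlation, 0.164 with the length trend removed at a median of 0.06, and 0.0880 or 0.0812 without 30 s replicate 2 or 3 min replicate 3). These were Serpinh1, a collagen chaperone (0.21), Tnc (0.46) and Col6a3 (0.27), whose calls ended in 2, 4 and 5 of the 6 cases with 1 library left out (edgeR adjusted p of up to 0.179 and 0.252 without 30 s replicate 2 and 0.318 without 30 s replicate 1).

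From 3 to 30 min, 4 of 25 stress response genes, 44 of 79 ribosomal protein mRNAs and 34 of 73 respiratory chain mRNAs rose by edgeR. Ddit3, the proapoptotic factor CHOP, rose from 16.5 ± 5.1 to 44.1 ± 12 CPM (log2 1.40 ± 0.22, edgeR adjusted p = 5.16e-06), and Nupr1 and Atf4 rose by 1.14 ± 0.14 and 0.67 ± 0.05. Chac1 rose by 1.30 ± 0.31 (edgeR adjusted p = 0.0857 without 30 min replicate 2). In the stress response list 4 rose and none fell by edgeR (6 and 1 adjusted over the list alone). The median was 0.12 (camera adjusted p = 0.00112; adjusted p = 0.0351 with an estimated correlation). Of ribosomal mRNAs 44 rose and 8 fell (48 and 15 adjusted over the list alone). The median was 0.28 (camera adjusted p = 4.93e-22; adjusted p = 0.0351 with an estimated correlation), and 0.15 with the length trend removed. Of respiratory chain mRNAs 34 rose and 2 fell (37 and 6 adjusted over the list alone). The median was 0.28 (camera adjusted p = 3.75e-15; adjusted p = 0.0351 with an estimated correlation). It was 0.06 with the length trend removed, 0.0094 without mRNAs of 800 nt or less and 0.16 without genes that have a copy. Rps18, without a near-identical copy, rose from 765 ± 23 to 1230 ± 61 CPM and Cox6a1 from 344 ± 25 to 588 ± 9.1 CPM. The 108 other short mRNAs had a median of 0.33, with 57 higher and 1 lower (0.04 by the first length measure). Of the G2/M list 4 fell (9 adjusted over the list alone). The median was -0.07 (camera adjusted p = 0.0164; adjusted p = 0.0351 with an estimated correlation, 0.0590 without 3 min replicate 3 and 0.0761 without genes that have a copy, at a median of -0.07). Tubb4b, Kif11, Top2a and Ndc80 fell by 0.53, 0.50, 0.25 and 0.52. The calls of the last 3 ended with 1 library left out in 2, 3 and 3 of the 6 cases, with edgeR adjusted p of up to 0.160 without 3 min replicate 3, 0.128 without 30 min replicate 3 and 0.0874 without 30 min replicate 2. By edgeR 285 genes rose and 121 fell, 20 and 4 of them pseudogenes. With the length trend removed 208 rose and 142 fell, and 260 genes were called without mRNAs of 800 nt or less. Falls were as few as 75 with 1 library left out (3 min replicate 1).

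Compared with 3 min in trypsin, low trypsin gave higher ribosomal and respiratory chain mRNAs and 69 pseudogenes that rose by edgeR. Of ribosomal mRNAs 49 rose and 5 fell (53 and 10 adjusted over the list alone). The median was 0.37 (camera adjusted p = 4.04e-32; adjusted p = 0.0119 with an estimated correlation), 0.08 with the length trend removed and 0.25 without mRNAs of 800 nt or less. Of respiratory chain mRNAs 40 rose and none fell by edgeR (45 and 2 adjusted over the list alone). The median was 0.31 (camera adjusted p = 1.61e-30; adjusted p = 0.00323 with an estimated correlation), and those settings gave 0.09 and 0.11. Rps20, without a near-identical copy, rose from 658 ± 21 to 1131 ± 69 CPM and Ndufa7 from 114 ± 7.6 to 212 ± 6.6 CPM. The 108 other short mRNAs had a median of 0.39, with 70 higher and 2 lower (0.02 by the first length measure). In the mitochondrial list 6 rose (7 adjusted over the list alone). The median was 0.21 (camera adjusted p = 5.07e-05; adjusted p = 0.0190 with an estimated correlation, and 0.0934 without mRNAs of 800 nt or less or 0.0724 with the length trend removed, at medians of 0.08 and 0.11). mt-Co2, mt-Cytb, mt-Co3 and mt-Nd1 rose by 1.22, 0.42, 0.50 and 0.27. Of G2/M genes 4 fell and 1 rose (5 and 1 adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.000175; adjusted p = 0.00323 with an estimated correlation). Mki67, the proliferation marker, fell by 0.57 ± 0.13, Cdc20 by 0.26 ± 0.06 and Cenpf by 0.38 ± 0.09 (edgeR adjusted p of up to 0.0678 in 2 cases, without 3 min replicate 2). None of 17 muscle genes passed by edgeR (none adjusted over the list alone). The median was -0.21 (camera adjusted p = 0.0423; adjusted p = 0.0837 with an estimated correlation). The list lost its call without 3 min replicate 2 (0.113), 3 min replicate 3 (0.138) or low trypsin replicate 3 (0.382) and with the filter of 10 CPM (0.154). Its median was -0.33 without mRNAs of 800 nt or less and -0.36 with the length trend removed. By edgeR 381 genes rose and 58 fell, of which 69 and none were pseudogenes. A total of 273 rose and 83 fell with the length trend removed, and 261 genes were called without mRNAs of 800 nt or less. The 58 falls were 31 with DESeq2 and as few as 23 with 1 library left out (low trypsin replicate 1).

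Compared with 3 min in trypsin, cells in the cold-active protease had higher ribosomal and respiratory chain mRNAs and lower Ccn1 and Hes1. Ccn1 fell from 405 ± 13 to 228 ± 16 CPM (log2 -0.83 ± 0.07, edgeR adjusted p = 1.04e-14) and Hes1 from 84.0 ± 8.6 to 57.9 ± 7.4 CPM (log2 -0.52 ± 0.12, edgeR adjusted p = 0.00251). Srf fell by 0.73 ± 0.19, a call that ended in 4 of the 6 cases with 1 library left out (up to 0.226, without 3 min replicate 1). These were the 2 genes of the immediate early list that fell (2 adjusted over the list alone). The median was -0.09 (camera adjusted p = 0.0225; adjusted p = 0.163 with an estimated correlation, and 0.0589, 0.172 and 0.171 without 3 min replicate 1, 3 min replicate 3 and cold-active protease replicate 3). Of ribosomal mRNAs 49 rose and 1 fell (53 and 5 adjusted over the list alone). The median was 0.41 (camera adjusted p = 2.5e-50; adjusted p = 0.00285 with an estimated correlation), and 0.17 with the length trend removed. Of respiratory chain mRNAs 41 rose and 1 fell (45 and 2 adjusted over the list alone). The median was 0.36 (camera adjusted p = 1.04e-33; adjusted p = 0.00285 with an estimated correlation). It was 0.06 with the length trend removed and 0.06 without mRNAs of 800 nt or less. Rps13, without a near-identical copy, rose from 478 ± 21 to 899 ± 33 CPM and Uqcrq from 183 ± 23 to 343 ± 12 CPM. The 108 other short mRNAs had a median of 0.40, with 67 higher and 1 lower (0.05 by the first length measure). Of G2/M genes Kif11 and Hmgb2 fell by 0.48 and 0.32 (2 adjusted over the list alone). The median was -0.08 (camera adjusted p = 0.0225; adjusted p = 0.0271 with an estimated correlation, and 0.0589, 0.123 and 0.101 without 3 min replicate 1, without 3 min replicate 3 and without genes that have a copy, the last at a median of -0.07). Both gene calls ended with 1 library left out, at edgeR adjusted p of up to 0.214 without 3 min replicate 3 and 0.392 without 3 min replicate 1. In the list of nuclear-retained RNAs the snoRNA host genes Snhg1 and Gas5 rose by 0.67 and 0.38 (2 adjusted over the list alone). The median was 0.13 (camera adjusted p = 0.0427; adjusted p = 0.163 with an estimated correlation). Gas5 had an edgeR adjusted p of 0.219 without cold-active protease replicate 3. That list lost its call without 3 min replicate 1, 3 min replicate 3, cold-active protease replicate 2 and cold-active protease replicate 3 (0.0922, 0.276, 0.130 and 0.0992), and without 3 min replicate 3 its median was -0.04. By edgeR 286 genes rose and 87 fell, 9 and 4 of them pseudogenes. With the length trend removed 165 rose and 115 fell, and 200 genes were called without mRNAs of 800 nt or less. The 87 falls were 50 with DESeq2 and as few as 43 with 1 library left out (cold-active protease replicate 2).

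Several lists gave no call in any comparison. The 13 lists tested without a call covered cold-inducible RNA-binding proteins, the oxidative stress response of Nrf2, p53 targets, apoptosis regulators, SRF targets and the actin cytoskeleton, integrins and focal adhesion, myoblast identity, S phase, replication-dependent histones, glycolysis and hypoxia, the hypotonic and ion response, adipogenic markers and fibroblast markers. Their medians lay between -0.42 and 0.34 and their lowest camera adjusted p was 0.0524, for glycolysis and hypoxia. Over the 9 comparisons, rises and falls of single members by edgeR numbered, in that order of lists, 4 and 2, 10 and 14, 3 and 0, 0 and 1, 11 and 16, 3 and 0, 6 and 3, 5 and 5, 1 and 2, 14 and 12, 5 and 0, 0 and 0, and 0 and 0. Adjusted over the list alone they were 9 and 5, 16 and 16, 3 and 0, 0 and 1, 17 and 29, 4 and 1, 7 and 6, 6 and 6, 2 and 3, 15 and 13, 6 and 0, 0 and 0, and 0 and 0. Lists of protease-activated receptors, haematopoietic, endothelial, osteogenic and epithelial markers had 1, 1, 0, 2 and 2 tested members and were not tested. Of these, F2r rose in 2 comparisons by edgeR (3 adjusted over the list alone), and no other member passed by edgeR over all genes. Adjusted over the list alone, the epithelial list had 1 rise and 1 fall. The adipogenic and fibroblast lists had 4 and 3 tested members. Jun, Myc, Hspa1b, Myod1, the myogenic regulator, and Cirbp passed in no comparison against control. Myod1 had 50.6 ± 5.3 CPM in control and 53.5 to 63.0 CPM in the treated groups.

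Some changes were shared between treatments. Sh3bgrl3 and Ppp1ca were lower in all 5 treatments by edgeR, Sh3bgrl3 at 19.8 to 37.8 CPM against 67.1 ± 0.56 in control. Over the 10 pairs of comparisons against control, 1386 calls were shared in the same direction and 41 were opposite. Simulated counts without a change between groups shared 2.05 calls, and independent lists of these sizes would share 86.5. All 18 libraries, controls included, were redrawn around a common mean per gene. The simulation therefore holds the sampling of shared controls but no deviation particular to the real ones. Covariances of the fold changes were 0.0337 to 0.0822 against 0.0237 to 0.0240 in the simulations. Correlations were 0.380 to 0.680 against 0.475 to 0.518, and in 6 of the 10 pairs they lay below the simulated value. The 3 controls cannot be split into sets of 2 libraries each, so part of the excess may come from the shared controls.

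The positions of the genes described most were, on GRCm38, chromosome 16, 30064384 to 30067796 for Hes1; chromosome 5, 90891241 to 90893115 for Cxcl1; chromosome 15, 80255184 to 80257541 for Atf4; chromosome 10, 127290774 to 127296288 for Ddit3; and chromosome 3, 145646976 to 145649981 for Ccn1. Egr1 lies on chromosome 18 from 34859823 to 34864984, Dusp1 on chromosome 17 from 26505590 to 26562128, Chac1 on chromosome 2 from 119351229 to 119354381, and Crtc2 on chromosome 3 from 90254163 to 90264125. Sh3bgrl3 lies on chromosome 4 from 134127406 to 134128789, Ppp1ca on chromosome 19 from 4192065 to 4195420, Col12a1 on chromosome 9 from 79598991 to 79718831, and Plau on chromosome 14 from 20836660 to 20843385. Reads of BRB-seq fall mainly in the annotated 3' UTR and last exons of such genes. Exons within the last 400 nt overlapped another gene on the opposite strand for Sh3bgrl3 (188 nt of Ubxn11), Ppp1ca (225 nt of Rad9a), Ndufb6 (257 nt of Smim27), Junb (173 nt of Prdx2), Ddit3 (68 nt of Mars), Polr2j, Naa38, Cox5a, Cox6c, Trmt112, Dhps, Noc2l, Nsa2 and Prc1, among others, and the values of these genes are uncertain. So are those of further named genes with near-identical copies, namely Sap18b, Tmsb10, Cox6c, Cox7c, Uqcr11, Ndufs5, Hmga1b, Nsa2, Noc2l, Hsp90aa1, Myl1, Bcl7c, Btf3, Nudt21, Kif11, Ndc80, Tubb4b, Wdr89, Kpna2 and mt-Co3.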

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

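The results in this part were picked out because 2 treatments differed when tested directly against each other with edgeR or camera. The tests on mRNA length, time in trypsin, preparation by group and, except for pseudogenes, near-identical copies were chosen after the result had been seen.

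Between 3 min and 30 s of trypsin, edgeR called 195 genes. Noc2l, mt-Rnr1, Prc1, Mir6236 and Actg1 were higher at 3 min by log2 1.52, 1.38, 1.277, 1.09 and 1.003. mt-Tq, Rps27rt, mt-Nd3, Plau and Wdr89 had -1.35, -1.284, -1.19, -1.11 and -0.92. The calls of Noc2l, mt-Rnr1, Prc1 and mt-Tq ended with 1 library left out in 3, 1, 4 and 4 of the 6 cases, with edgeR adjusted p of up to 0.423 for Noc2l without 3 min replicate 2. The medians that differed by camera were 0.0896 for matrix genes, -0.0810 for the respiratory chain and -0.0270 for ribosomal proteins. None of these calls held with an estimated correlation (adjusted p = 0.122, 0.265 and 0.947 by camera).

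Between 30 and 3 min, edgeR called 406 genes. Depp1, Cxcl1, Hes1, Sulf2, an enzyme that trims heparan sulfate, and Dusp1 were higher at 30 min by 2.54, 2.48, 1.93, 1.53 and 1.4998. Bccip, Kpna2, Mir6236, Phtf2 and Ftl1 had -1.53, -1.36, -1.21, -1.12 and -1.02. The calls of Sulf2, Bccip, Kpna2 and Phtf2 ended in 4, 3, 4 and 3 of the 6 cases, with edgeR adjusted p of up to 0.186 for Phtf2 without 3 min replicate 1. Medians that differed by camera were 0.12 for stress response genes, 0.28 for the respiratory chain, 0.28 for ribosomal proteins and -0.0723 for G2/M genes.

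Between low trypsin and 3 min, edgeR called 439 genes. Nkain2, Usp50, Rps27rt, Hmga1b and Smim4 were higher in low trypsin by 3.31, 1.75, 1.66, 1.51 and 1.43, and Nkain2 lay below 3 counts in 2 of the 3 libraries at 3 min (0.994 ± 0.67 CPM). Noc2l, Nsa2, Zbtb22, Trmt10a and Atoh8 had -1.72, -0.99, -0.78, -0.77 and -0.70. The calls of Smim4, Noc2l, Nsa2, Zbtb22, Trmt10a and Atoh8 ended in 1, 1, 4, 2, 1 and 2 cases, with edgeR adjusted p of up to 0.224 for Nsa2 without low trypsin replicate 2. Camera set apart muscle genes (-0.21), mitochondrially encoded transcripts (0.21), the respiratory chain (0.31), ribosomal proteins (0.37) and G2/M genes (-0.11). The call of the muscle list, of which no member passed, was lost with an estimated correlation (camera adjusted p = 0.0837).

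Between the cold-active protease and 3 min, edgeR called 373 genes. H2aj, Snrpd2, Psmg4, Anapc13 and Tmem171 were higher in the cold-active protease by 1.20, 1.06, 1.04, 1.01 and 0.99. Cep44, Rnaseh1, Loxl2, a lysyl oxidase of the matrix, Ccn1 and Trrap had -1.09, -0.97, -0.88, -0.83 and -0.75. The calls of Cep44, Rnaseh1, Loxl2 and Trrap ended in 2, 1, 5 and 3 cases, with edgeR adjusted p of up to 0.275 for Loxl2 without cold-active protease replicate 1. By camera, medians differed for immediate early factors (-0.0858), the respiratory chain (0.36), ribosomal proteins (0.41), G2/M genes (-0.0757) and nuclear-retained RNAs (0.13). The first and the last of these calls were lost with an estimated correlation (camera adjusted p = 0.163 for each).

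Lower ribosomal protein and respiratory chain mRNAs at 30 s and 3 min could stem in part from mRNA length, since 108 other mRNAs of 800 nt or less, with log2 CPM above 6, had a median of -0.41 at 3 min by the principal isoform, although by the first measure, the median isoform, 445 short genes had -0.07, so the 2 measures gave opposite answers. Length is not the whole cause for ribosomal mRNAs: with its trend removed their median was still -0.22 at 3 min (camera adjusted p = 2.66e-22), and the longer members had -0.34. At 30 s ribosomal members under 400 nt had 0.54. The 1 respiratory chain gene and 1 other coding gene of that length also lay above control, at 0.58 and 0.16. The values under 400 nt therefore do not separate length from another cause. Reads shared with annotated copies do not account for the pattern, since the 69 members without such a copy had -0.51 at 3 min. Copies outside annotated transcripts or beyond the isoform searched were not looked for, so shared reads are not excluded. An effect that grows with time in trypsin does not account for the pattern either, since the short mRNAs had -0.0837 at 30 min. Preparation of RNA or libraries by group could not be told from an effect of trypsin on the cells: the highest of the 6 libraries at 30 s and 3 min lay at -0.28 relative to control.

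Pseudogenes were called in several groups, 88 of 159 against control. Those called had a near-identical coding gene in 84.1% of cases and the others in 71.8%, a difference of 12.3 points. This met the prediction written beforehand for reads shared with copies (over 10 points), but its Fisher's exact p was 0.0797, a condition added after the value had been seen, so the question stays open. The coding copy moved the same way by at least 0.5 times as much on the log2 scale in 27 of 146 cases, 18.5%. By the prediction written beforehand this counts against a change of the parent gene as the source of most calls. Calling selects large pseudogene changes and uncalled pseudogenes were not compared, so a change of the parent is not excluded. No biological explanation was tested.

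Higher stress response genes at 30 min did not come from mRNA length, with a median of 0.23 after the length trend was removed. Nor did they come from annotated copies, with 0.21 for members without one. No single library made the pattern, since the lowest median with 1 library left out was 0.18. Preparation by group, which is confounded with treatment, could not be separated from 30 min in trypsin as the biological explanation.

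Whether chance alone could give such counts was examined by regrouping the 6 libraries of each comparison in all 10 possible ways, which cannot give a share under 0.05. The true grouping was the 1 of 10 with the most calls in each comparison. It gave 699, 399, 472, 523, 67, 195, 406, 439 and 373 calls, in the order of the comparisons in the methods, and the highest other grouping gave 3, 2, 5, 2, 4, 2, 0, 0 and 0. For any difference among the 6 groups, 1 of 100 groupings reached 1158 calls, the true one, and the highest other gave 115. Random assignment of single libraries to groups therefore does not account for it. If the lots of a group shared a culture or preparation, chance differences between cultures or preparations would pass this test too. Such differences are not excluded.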

How the results depend on the processing

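The settings without short mRNAs, without near-identical copies and with the length trend removed were chosen after seeing the data. No call by edgeR or camera turned to the opposite direction. Medians crossed 0 in these cases under the added settings: mitochondrially encoded transcripts without short mRNAs in low trypsin (-0.0016, still called) and at 30 s (-0.11), heat shock at 30 s without copies (0.01), and ribosomal mRNAs for 3 min against 30 s without short mRNAs (0.07) and with the length trend removed (0.05). Total counts of called genes stayed within 1.5 times under other scaling, filters, DESeq2, limma-voom, fits of the compared groups alone and the replicate block. Over the planned settings, 168 of 176 counts stayed within 1.5 times, and 533 of 612 list results and 5105 of 5471 gene results kept their side of the threshold. Under the added settings 19 of 33, 128 of 150 and 861 of 899 did. Of 302 calls of named genes, 208 held under every setting, and of 51 list calls 23 did. Leaving out 1 library ended 90 of these gene calls, and the added settings ended 26. DESeq2 ended 29, no filter 17 and removal of the length trend 20. For single genes the results above give only the losses with 1 library left out.

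Tested only on coding genes without a near-identical copy, the counts were 444 at 30 s, 244 at 3 min, 282 at 30 min, 312 for low trypsin, 24 for the cold-active protease, 72 for 3 min against 30 s, 252 for 30 against 3 min, 221 for low trypsin against 3 min and 238 for the cold-active protease against 3 min. Without mRNAs of 800 nt or less they were 202 at 3 min, 129 for 3 min against 30 s, and 260, 261 and 200 for 30 min, low trypsin and the cold-active protease against 3 min. Both settings test fewer genes. Of the list tests, 51 passed camera with the preset correlation, 29 with an estimated one, 79 passed fry and 155 fry in either direction, which asks another question.

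With 1 library left out, counts ran from 537 to 633 at 30 s, 290 to 375 at 3 min, 304 to 394 at 30 min, 361 to 463 for low trypsin and 35 to 54 for the cold-active protease. They ran from 145 to 152 for 3 min against 30 s, 311 to 363, 339 to 426 and 277 to 330 for 30 min, low trypsin and the cold-active protease against 3 min, 1045 to 1150 over all groups and 42 to 60 for list tests. Leaving out a library also lowers the power of the test.

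Replicate numbers did not pair the libraries: 45 same-number pairs correlated at -0.12 to 0.12, and 7 of 18 libraries correlated best with their own number. With the replicate block the counts were 688, 378, 459, 526, 63, 183, 404, 432 and 365, 1129 over all groups, 47 list tests and 1336 shared calls. The block ended 4 list calls. These were mitochondrially encoded transcripts at 3 min (camera adjusted p = 0.0504, median 0.14) and ribosomal proteins for 3 min against 30 s (0.0680, -0.03). The others were the respiratory chain in low trypsin (0.0547, -0.04) and nuclear-retained RNAs for the cold-active protease against 3 min (0.0519, 0.13). At this depth and 3 libraries per group, 46% of genes changed 1.5-fold in simulated counts were recovered, and which of these limited the calls was not tested. Genes under 1.21 to 2.01 CPM lay below 3 counts.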

Other observations

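The genes in this part were chosen after their values had been seen. Several stress genes beyond those already described were higher at 30 min by edgeR. Ddit4, an inhibitor of mTORC1, rose from 61.9 ± 3.4 to 113 ± 17 CPM (log2 0.87 ± 0.12, edgeR adjusted p = 5.36e-07), Gdf15, a stress cytokine, from 33.9 ± 6.0 to 57.6 ± 3.1 CPM (log2 0.78 ± 0.16) and Trib3, an Atf4 target, by 1.44 ± 0.45 (edgeR adjusted p = 0.0467). Myf5, a myogenic regulator, rose by 0.71 ± 0.12 at 30 s and 0.79 ± 0.12 at 30 min. Tagln, the actin-binding protein SM22, rose from 20.98 ± 1.9 to 42.6 ± 7.4 CPM at 30 s and 53.6 ± 5.2 CPM in low trypsin (log2 1.03 ± 0.19 and 1.36 ± 0.18). Ccn2 and F3 rose by 0.75 ± 0.11 and 0.81 ± 0.15 at 30 s, and Ccl2 was higher at 30 s, 3 min and 30 min (0.57, 0.50 and 0.37).

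Some pseudogenes had large differences from control in 1 or more groups. Gm13340, which resembles mt-Co1, had 11.3 ± 5.4 CPM in control, 45.9 ± 8.4 at 30 s, 14.2 ± 7.2 at 3 min, 205 ± 6.6 at 30 min, 28.5 ± 12 in low trypsin and 500 ± 25 in the cold-active protease (log2 5.52 ± 0.16, edgeR adjusted p = 1.5e-32). mt-Co1 did not pass in any comparison with control. Gm28437, which resembles mt-Co3, had 231 ± 81 CPM in control, 781 ± 80 at 30 s and 1470 ± 118 in low trypsin. Rpsa-ps2 had 1.23 ± 0.27 CPM in control, below 3 counts in 2 of the 3 libraries, and 52.1 ± 10 in low trypsin, and Rps12-ps2 2.40 ± 0.45 in control and 38.0 ± 4.7 at 30 min. The predicted genes Gm10800, Gm10801 and Gm21738 were lower in all 5 treatments by edgeR, Gm10800 at 1502 ± 557 CPM in control and 418 ± 102 in low trypsin. Gm10717 was lower in 4, with an edgeR adjusted p of 0.0536 at 30 s. Gm10800 and Gm10717 have 2 and 3 near-identical copies, and Gm10801 is a copy of Gm10800, so the values of these genes are uncertain. For Gm21738 the search found no annotated copy.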
